A study of Mus musculus with 2 samples.

How the data were processed

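RNA was sequenced from macrophages of mouse dorsal root ganglia in 2 libraries, 1 from mice under normoxia and 1 from mice under chronic intermittent hypoxia. Per the labels' protocols, RNA was extracted with TRIzol and chloroform and libraries were made with the NEBNext Ultra II RNA kit. No molecular identifiers are mentioned there, so copies of 1 starting molecule could not be merged and counting intervals cover counting error only. Per the submitters' processing notes, the tools were bcl2fastq 2.20, STAR 2.5.2b and featureCounts of Subread 1.5.2. The genome build, the annotation, the strand setting, any removal of duplicates and the way the macrophages were isolated are not given in the sources used here.

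The authors deposited whole-number read counts per gene for both libraries, 49315 genes in all, with no normalization. They also deposited TPM values (transcript abundances by gene length, scaled to the same total in each library) for the same genes. The TPM table had its zeros at the same genes as the count table (100%), and the ratio of TPM to count in hypoxia over that in normoxia lay between 11.48 and 11.49 for all genes checked, so TPM adds no separate measurement. The columns carry short codes in place of the sample titles. The code with the number 1 and the initial N was taken as normoxia, and the code with the initial C was taken as chronic intermittent hypoxia. The number in the latter, 19, matches neither sample's description, so its assignment rests on the initial alone. Gene symbols came from the deposited table, and 174 genes had no symbol, with 500 counts in normoxia and 0 in hypoxia. Positions and gene types came from GENCODE M21 on GRCm38, in which 49056 of the 49315 gene identifiers were found. The authors' build may differ.

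Counts were scaled by the trimmed mean of M values (TMM) with edgeR 4.0.16 in R 4.3.3, which gave factors of 0.757 for normoxia and 1.32 for hypoxia. Relative to total counts, TMM moves every log2 ratio of hypoxia over normoxia by −0.80. TMM draws on genes counted in both libraries, here 1158 genes. For each gene with at least 50 counts over both libraries, the ratio of scaled counts was given with an exact 95% interval (Clopper-Pearson, conditional binomial). A gene met the size rule when the ratio was at least 2-fold in either direction and the interval excluded 1. With 1 library per group there is no spread between replicates, so no p-value across conditions was computed and the differences have no replicate check. Log2 ratios used a prior count of 0.5. A count of 0 was taken to allow up to 3 counts, which is 1.38 CPM (counts scaled to a fixed library total) in normoxia and 20.7 CPM in hypoxia.

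In all, 40 gene lists were fixed before the data were examined, for macrophage states, other cell types of the ganglion and blood, and pathways. Each list's median log2 ratio over its measured members was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart when it lies below percentile 2.5 or above percentile 97.5. Percentiles describe these libraries only. Each list's share of total counts was given with an exact Clopper-Pearson interval. Genes were named by a rule fixed in advance, namely the 12 highest and 12 lowest ratios among genes that met the size rule with at least 200 counts, every measured marker of the M1 and M2 lists, up to 4 members with most counts and 2 with the largest ratio of each other list, 7 genes fixed by name (Nos2, Tnf, Il1b, Il6, Arg1, Mrc1 and Il10), and the 5 genes with most counts in each library. Predicted genes, pseudogenes, ribosomal, mitochondrial and immunoglobulin or T cell receptor genes were left out of the highest and lowest genes. Genes outside this rule (Lcn2, Dock10, Ylpm1, Psap, Mmp8, Mpo, Fosb, mt-Nd6, mt-Co2, mt-Co3 and mt-Atp6) were named after their values were seen. Not every gene that the rule names is given in the text.

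After the data were seen, an estimate of reads per starting molecule was added. It is the median count of genes counted in 1 library alone with at least 10 counts, and rests on the untested assumption that such genes mostly stem from 1 molecule. Intervals on estimated molecules divide counts by this number first, and were computed with TMM and with total counts. Also added after the data were seen were a repeat on genes counted in both libraries only, a repeat of each list's share without its member with most counts, medians with each 0 taken as 3 estimated molecules (807 CPM in hypoxia), and a comparison of each list, and of the housekeeping and ribosomal protein genes with at least 500 counts, with 10000 draws of genes matched on their counts in normoxia (50 nearest genes). Lists were also compared with genes matched on counts in hypoxia, which is given only with the mitochondrially encoded genes. Genes with near-identical copies, such as the globins and Ear2, may share reads and their values are uncertain.

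The scripts were tested on simulated data. With reads drawn by Poisson sampling over 4527 measured genes, the size rule recovered 50.0% of 2-fold, 97.9% of 4-fold and 100% of 8-fold increases and 85.1% of decreases to 0.25 of normoxia, and called 26 unchanged genes higher and 35 lower. With no difference but molecules copied as estimated, over 2929 measured genes, the rule on reads called 617 genes higher and 1677 lower. On estimated molecules with total counts it called 50 higher and 1 lower, and 98.3% of the intervals held the true ratio. The simulation used the same reads per molecule as the intervals, so this share is built in and does not test the estimate. It counted 2857 genes in normoxia and 1724 in hypoxia, against 4640 and 2050 in the libraries, so it does not reproduce them. Of 200 lists drawn at random from the measured genes of the real data, 4% lay outside percentiles 2.5 to 97.5. They came from the same pool as the lists they were ranked against, so this checks the calculation only.

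Alternatives planned before the data were examined were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, TMM without mitochondrially encoded genes, scaling to the housekeeping list, the deposited TPM ratio, other count minimums, fold limits, interval levels and prior counts, list means, 50 expression bins, random lists without predicted genes, and marker lists without shared members. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.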

Results

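Gene expression was measured in macrophages from mouse dorsal root ganglia, the clusters of sensory nerve cell bodies beside the spinal cord, after chronic intermittent hypoxia or normoxia. Chronic intermittent hypoxia is a model of the repeated oxygen dips of sleep apnoea. Chamber oxygen cycled between 21% and 8% with a period of 6 min, 10 times per hour, for 8 h daily over 14 days, and the normoxia mice stayed at 21% in the same chambers. Samples were taken about 18 h after the last exposure. There was 1 library per group, so no difference has a replicate check, and every interval covers counting error only. How many mice gave each library is not given in the sources used here. The hypoxia column was assigned by the initial of its code alone.

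The normoxia library held 2171348 counts and the hypoxia library 145056, a 15.0-fold difference in depth. In normoxia 4640 genes were counted and in hypoxia 2050, of which 1158 were counted in both. The median count of a counted gene was 230 in normoxia, with quartiles of 114 and 439, and 42 in hypoxia, with quartiles of 23 and 61. Genes with 1 to 9 counts made up 443 (9.55%) of the counted genes in normoxia and 243 (11.9%) in hypoxia. With an estimate of 229 and 39 reads per starting molecule, the libraries came to about 9482 and 3719 molecules. At 3 such molecules, a gene in the hypoxia library holds 807 CPM (counts scaled to a fixed library total). The absence of a gene that holds less than that in normoxia is within what so few molecules allow. The list ratios below are shares of total counts in hypoxia over normoxia, with 95% intervals on estimated molecules. TMM scaling multiplies each of them by the same factor, as does scaling to the housekeeping list, and these are given where they turn a direction or move an interval across 1. The intervals leave out the uncertainty of these factors, which is wide for the housekeeping list.

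**Figure D1:**
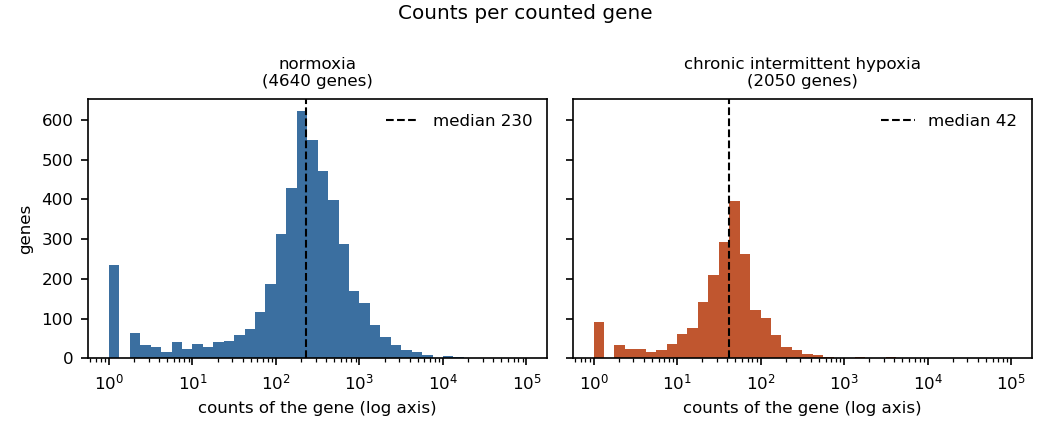
Number of genes (vertical axis) by their count (horizontal log axis) in the normoxia library (left, 4640 genes) and the chronic intermittent hypoxia library (right, 2050 genes). The dashed lines mark the medians of 230 and 42, and genes with 1 to 9 counts are few beside the genes around the median.

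The series title names M1 polarization, the shift of macrophages to a pro-inflammatory state, as the question of the comparison. M1 markers took 0.181% of counts in normoxia (95% interval 0.176 to 0.187) and 0.122% in hypoxia (0.105 to 0.141), a ratio of 0.674 with an interval of 0.182 to 1.97. Markers of alternative (M2) activation took 0.357% (0.349 to 0.365) and 0.421% (0.388 to 0.455), a ratio of 1.18 (0.604 to 2.21). The intervals of the shares, which are on reads, lie apart for both lists, whereas the intervals of both ratios on estimated molecules include 1. The estimated number of molecules in the hypoxia library is too low to show a difference in most of the markers. With TMM the ratios were 0.386 and 0.676, and with housekeeping scaling they were 1.18 and 2.06, the latter with an interval of 1.06 to 3.86. Without the member with most counts, Cybb in M1 and Chil3 in M2, the ratios on total counts were 0.314 (0.014 to 1.90) and 0.553 (0.145 to 1.61), so the direction of the M2 ratio on total counts rests on Chil3. With TMM the latter was 0.317 (0.083 to 0.924). In hypoxia Cybb held 72.3% of the M1 counts and Chil3 72.6% of the M2 counts. The lists describe the libraries and no cell was typed. Whether these counts came from macrophages or from other cells, such as neutrophils, was not tested.

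Of 30 M1 markers, 10 were counted in normoxia, 2 in hypoxia and 1 in both. By the size rule on reads, 8 of the 9 measured markers were lower in the hypoxia library, each with 0 counts there, none was higher, and 1 met neither. That 1 was Cybb, the catalytic subunit of the phagocyte NADPH oxidase (ENSMUSG00000015340, chromosome X, 9435252 to 9487771 on GRCm38, as are all positions here), with 1594 counts in normoxia and 128 in hypoxia, a ratio of 0.689 (0.571 to 0.825 on reads). On total counts it held 734 and 882 CPM, so its direction turns with the scaling. The cytokine gene Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) had 334 counts in normoxia and 0 in hypoxia. The other 7 with 0 in hypoxia were the interferon regulatory factors Irf1 (542 counts in normoxia) and Irf5 (248), the formyl peptide receptor Fpr2 (470), the Fc receptor Fcgr1 (377), the costimulatory receptor Cd40 (196), Socs3 (100) and Tlr4 (70). The highest of these 8, Irf1, held 249.6 CPM in normoxia, below the 807 CPM of 3 molecules in hypoxia. Nos2, the inducible nitric oxide synthase, and the cytokine genes Il1b and Il6 had 0 counts in both libraries.

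Of 29 M2 markers, 11 were counted in normoxia, 4 in hypoxia and 3 in both. By the size rule on reads, 1 of the 10 measured markers was higher in the hypoxia library, 7 were lower, all with 0 counts there, and 2 met neither. The higher marker was the ribonuclease gene Ear2 (ENSMUSG00000072596, chromosome 14, 44102654 to 44103534), with 48 counts in normoxia and 115 in hypoxia, a ratio of 20.5 (14.6 to 29.4 on reads). It belongs to a family of close copies, and it was not among the genes that passed on estimated molecules. The chitinase-like gene Chil3 had 3223 and 443 counts, a ratio of 1.18 (1.06 to 1.30 on reads), and the scavenger receptor gene Cd36 had 299 and 45, a ratio of 1.29 (0.922 to 1.77). The markers with 0 in hypoxia were the fibronectin gene Fn1 (1601 counts in normoxia), the scavenger receptor gene Cd163 (928), the mannose receptor gene Mrc1 (584), Mgl2 (428), Il4ra (290), Tgm2 (166) and Stat6 (132). Arg1 and Il10 had 0 counts in both libraries.

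The median log2 ratio was −8.12 for the M1 list and −7.94 for the M2 list with a prior count in place of each 0. As upper limits, the medians were −3.27 and −3.09 with each 0 taken as 3 reads, and 1.59 and 1.01 with each 0 taken as 3 estimated molecules, so depth alone does not account for the direction, while the estimated number of molecules leaves it open. Among random lists of matched expression these medians lay at percentiles 85.3 and 21.8, so neither list stood apart. Members at 0 in hypoxia were there matched mostly with other genes at 0, so these percentiles cannot show a loss that such genes share. The M1 median minus the M2 median was −0.18, at percentile 88.4 of pairs of random lists, whose middle 95% ran from −2.84 to 0.38. Of the M1 markers counted in normoxia, 1 of 10 was also counted in hypoxia, against a median of 2 (0 to 5) in genes matched on their normoxia counts. For M2 it was 3 of 11, against 4 (1 to 6). Of the markers, 12 on the M1 and 8 on the M2 list are also on another list. The percentile of the M1 list ran from 11.5 to 94.1 over the alternatives.

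**Figure D2:**
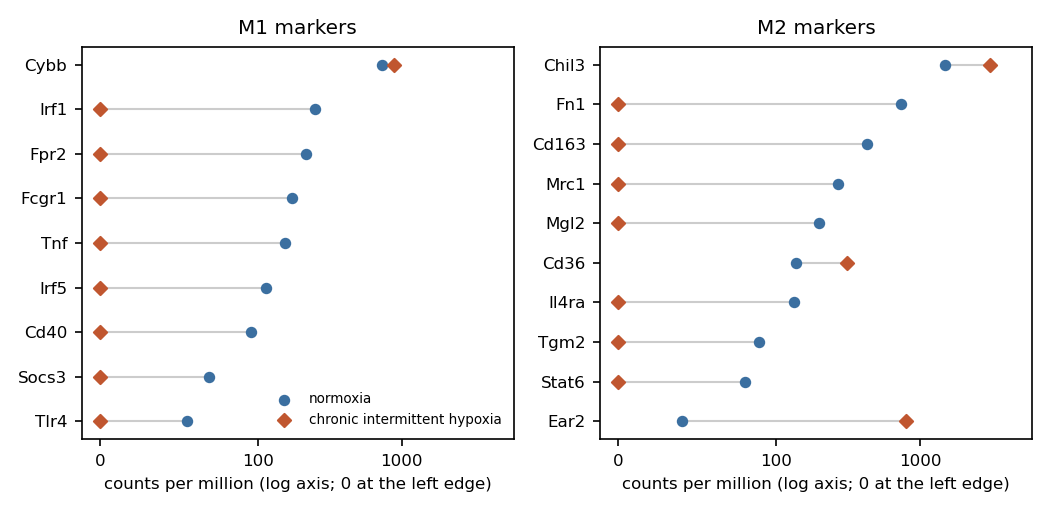
CPM (log axis, with 0 drawn at the left edge) of the 9 measured M1 markers (left) and the 10 measured M2 markers (right) in the normoxia library (circles) and the hypoxia library (diamonds). In hypoxia 8 of the M1 and 7 of the M2 markers lie at 0 counts.

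Neutrophil genes took a larger share of the hypoxia library, 9.36% of counts (9.21 to 9.51) against 1.71% (1.69 to 1.73) in normoxia, a ratio of 5.48 (4.53 to 6.64). The ratio was 3.14 with TMM and 9.58 with housekeeping scaling. The calprotectin genes S100a8 and S100a9, adjacent on chromosome 3 and abundant in neutrophils, were 3.05-fold and 3.09-fold higher after TMM. S100a8 (ENSMUSG00000056054, 90668978 to 90670035) had 10004 counts in normoxia and 3561 in hypoxia, with an interval of 2.94 to 3.17 on reads and 2.11 to 4.48 on molecules. S100a9 (ENSMUSG00000056071, 90692632 to 90695721) had 11656 and 4197, with 2.98 to 3.20 on reads and 2.19 to 4.40 on molecules. The granule protein genes Ngp (6932 and 3060 counts) and Camp (2878 and 1441) were 3.79-fold (2.46 to 5.96 on molecules) and 4.29-fold (2.21 to 8.90) higher. Of 10 measured list members, 7 were higher by the size rule, among them Ly6g with 0 counts in normoxia and 110 in hypoxia. The 3 others were lower, with Mmp9 at 522 and 0, Mmp8 at 312 and 0 and Mpo at 506 and 0. The list median was 1.497 on the log2 scale, at percentile 100 of random lists, whereas the list mean was −0.70, since the 3 members at 0 pull it down.

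Macrophage identity genes were mostly missing from the hypoxia library, within the range of other genes of their abundance. All 25 measured members of the pan-macrophage list were counted in normoxia and 10 in hypoxia, against 13 (9 to 17) in matched genes. By the size rule on reads 20 were lower, 15 of them with 0 counts in hypoxia, 1 was higher and 4 met neither. The list median of −8.09 lay at percentile 2.51, just inside the limit of 2.5, with a range of 0.075 to 3.35 over the alternatives. The macrophage surface receptor gene Adgre1, which encodes F4/80, had 1764 counts in normoxia and 0 in hypoxia, the lysosomal glycoprotein gene Cd68 had 1565 and 0, and the complement genes C1qa and C1qc had 1092 and 1253 in normoxia and 0 in hypoxia. The cathepsin gene Ctsb had 5770 and 81 counts, 8.31-fold lower on reads. As a share of counts the list took 3.18% and 2.80%, a ratio of 0.883 (0.700 to 1.11). Lyz2, a lysozyme gene that neutrophils also express, held 34028 of the list's 68956 counts in normoxia and 3164 of its 4068 in hypoxia. The ratio was 0.506 (0.401 to 0.634) with TMM and 1.54 (1.22 to 1.94) with housekeeping scaling, so its direction depends on the scaling. Without Lyz2 the list's ratio was 0.387 (0.239 to 0.602), below 1 with TMM (0.222) and with housekeeping scaling (0.677, with an interval of 0.418 to 1.05). Lipid- and injury-associated macrophage genes took 0.870% and 0.387% of counts, a ratio of 0.445 (0.235 to 0.785), led by the apolipoprotein gene Apoe (12776 and 249 counts). Without Apoe the ratio was 0.766 (0.301 to 1.73) on total counts, 0.439 (0.172 to 0.993) with TMM and 1.34 (0.526 to 3.03) with housekeeping scaling, so its direction depends on the scaling. With housekeeping scaling the ratio of the full list was 0.779, with an interval of 0.412 to 1.37, and 4 of its 11 members counted in normoxia were counted in hypoxia, against 4 (2 to 7) in matched genes. Monocyte genes took 0.570% of counts in both libraries (ratio interval 0.576 to 1.68), and the ratio was 0.574 (0.330 to 0.964) with TMM and 1.75 (1.01 to 2.94) with housekeeping scaling, with the chemokine receptor gene Ccr2 at 2308 and 0 counts. Tissue-resident macrophage genes had a ratio of 0.483 (0.098 to 1.62), or 0.277 (0.056 to 0.926) with TMM.

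**Figure D3:**
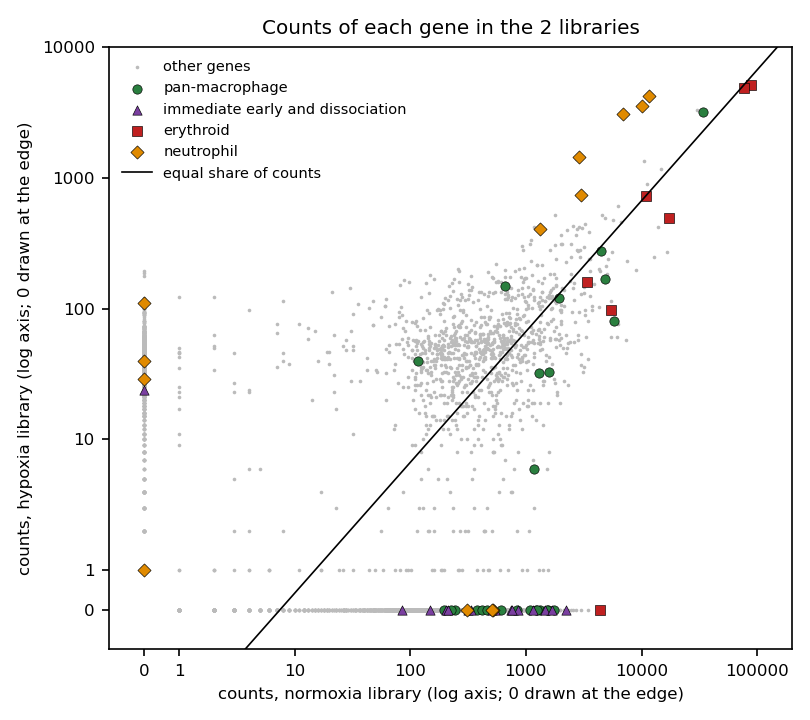
Counts of each gene in the normoxia library (horizontal log axis) and the hypoxia library (vertical log axis), with 0 drawn at the edges and the line marking equal shares of total counts. Of the neutrophil genes (orange diamonds) 6 were counted in both libraries and lie above the line, and 15 immediate early genes (purple triangles) lie at 0 in hypoxia.

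Red cell genes were abundant in both libraries. Erythroid genes took 9.53% of counts in normoxia (9.49 to 9.57) and 7.87% in hypoxia (7.73 to 8.01), a ratio of 0.826 (0.722 to 0.943) that was 0.473 with TMM and 1.44 (1.26 to 1.65) with housekeeping scaling. The globin genes Hbb-bs (88388 and 5121 counts) and Hba-a1 (77183 and 4826) had the most counts of any gene in each library. The band 3 anion exchanger gene Slc4a1 had 4373 counts in normoxia and 0 in hypoxia, and the haem synthesis gene Alas2 had 5450 and 97. Genes of the ganglion's own cells were near absent. Of 22 sensory neuron genes Isl1 alone was counted, with 0 and 60 counts, and of the Schwann cell genes Mbp had 0 and 58. The satellite glia genes Glul and Sparc had 129 and 85, and 183 and 42 counts. The ratio of the satellite glia list was 6.07 (0.621 to 139), or 10.6 (1.09 to 244) with housekeeping scaling. It rests on 1.37 and 3.26 estimated molecules. The 3 measured fibroblast genes, Col1a1 (375), Col1a2 (296) and Pdgfra (378), had 0 counts in hypoxia, at percentile 0.535 of random lists, with a range of 0.3 to 94.7 over the alternatives. Endothelial genes came to 3 counts in normoxia and 0 in hypoxia. T and NK cell genes and mast cell genes had 0 counts in both.

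Immediate early genes, which rise within minutes of cell stress or tissue dissociation, took 0.518% of counts in normoxia (0.509 to 0.528) and 0.0165% in hypoxia (0.0106 to 0.0246). The ratio was 0.032, with an upper limit of 0.265 on total counts and 0.463 with housekeeping scaling. All 15 members counted in normoxia had 0 counts in hypoxia, against 6 (3 to 10) counted among matched genes, at percentile 0.005. The phosphatase gene Dusp1 (ENSMUSG00000024190, chromosome 17, 26505590 to 26562128) had 2218 counts in normoxia, the mRNA decay factor gene Zfp36 had 1692, and the transcription factor genes Junb and Fos had 1464 and 1151. Fosb, with 0 counts in normoxia, was the only member counted in hypoxia, with 24. The list median of −9.24 lay at percentile 1.10, with a range of 0.050 to 6.60 over the alternatives.

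Mitochondrially encoded genes were lower in the hypoxia library, at 0.607% of counts (0.568 to 0.649) against 1.84% (1.82 to 1.86), a ratio of 0.330 (0.203 to 0.513) that stayed below 1 with TMM (0.189) and housekeeping scaling (0.577). Without mt-Co1 the ratio was 0.390 (0.213 to 0.667), or 0.681 with housekeeping scaling, with an interval of 0.372 to 1.17 that includes 1. The cytochrome c oxidase gene mt-Co1 had 16535 and 272 counts, 7.09-fold lower, and mt-Cytb had 7393 and 58, 14.9-fold lower. Of 7 measured members 6 were lower and 1 met neither, and the list lay at percentile 0.055 of random lists. That 1 was mt-Nd6, which went the other way, with 688 and 118 counts and a ratio of 1.47 (1.20 to 1.79 on reads). The genes mt-Co2, mt-Co3 and mt-Atp6 had 1, 6 and 3 counts in normoxia and 0 in hypoxia, so the share covers only part of the mitochondrial genes. Against genes matched on normoxia counts the list did not stand apart, with 6 of 10 members counted in hypoxia against 7 (5 to 8), and a median share ratio of 0.143 against 0.408, at percentile 5.93. Against genes matched on hypoxia counts it did. Its median share ratio of normoxia over hypoxia was 2.78 against 0.343, with an upper limit of 0.888, at percentile 100. The ribosomal protein and housekeeping lists lay at percentiles 99.5 and 99.3 there, so this matching does not single out mitochondrial genes. On scaling to the housekeeping list, mt-Nd1 and mt-Nd4 turned higher. Nuclear genes of oxidative phosphorylation had a ratio of 1.17 (0.667 to 1.98), or 0.668 with TMM and 2.04 (1.17 to 3.46) with housekeeping scaling, with 4 of 23 measured members higher, 13 lower and 6 neither. Their list median of −1.30 lay at percentile 98.9 (69.2 to 99.3 over the alternatives), and 12 members were counted in both libraries against 7 (3 to 11) in matched genes. Cytosolic ribosomal protein genes took 2.78% and 4.75% of counts, a ratio of 1.71 (1.40 to 2.07), which was 0.979 (0.804 to 1.19) with TMM. Of 38 such genes 36 were counted in hypoxia, against 23 (18 to 29) in matched genes, whereas for the housekeeping list it was 10 of 14, against 7 (5 to 10), at percentile 94.8.

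Among random lists, genes that respond to low oxygen did not stand apart. Targets of hypoxia-inducible factors had a ratio of 0.863 (0.400 to 1.73), and of 10 measured members 2 were higher, 7 lower and 1 neither, at percentile 70.8. Of the lower members 5 were at 0 in hypoxia and were there matched mostly with other genes at 0. The percentile therefore cannot show a loss that such genes share. Of the 10 members counted in normoxia, 5 were counted in hypoxia, against 3 (1 to 6) in genes matched on normoxia counts. The prolyl hydroxylase gene Egln3 had 652 counts in normoxia and 0 in hypoxia, Pfkfb4 had 621 and 0, the glycolytic enzyme gene Eno1 had 3700 and 105, and Ldha had 816 and 66. Glycolysis genes had a ratio of 1.06 (0.582 to 1.86), with 1 of 12 higher, 7 lower and 4 neither. Subunits of NADPH oxidase, the main source of superoxide in phagocytes, had a ratio of 0.826 (0.427 to 1.51), and antioxidant genes under NRF2 one of 0.908 (0.618 to 1.31). With TMM the ratios of these 4 lists were 0.495, 0.607, 0.473 and 0.520, and with housekeeping scaling 1.51, 1.85, 1.44 and 1.59, so their directions depend on the scaling. With TMM the intervals of the hypoxia-inducible factor targets (0.229 to 0.992), NADPH oxidase (0.245 to 0.865) and antioxidant genes (0.354 to 0.750) excluded 1. With housekeeping scaling those of glycolysis (1.02 to 3.24) and antioxidant genes (1.08 to 2.29) excluded 1 in the other direction. Without Eno1 the ratio of the hypoxia-inducible factor targets was 1.27 (0.493 to 3.01) on total counts, 0.726 with TMM and 2.22 with housekeeping scaling. The housekeeping genes had a ratio of 1.02 (0.760 to 1.36), or 0.586 (0.435 to 0.782) with TMM and 1.79 (1.33 to 2.39) with housekeeping scaling. Housekeeping scaling sets the list's median log2 ratio to 0 and not its ratio of shares, which therefore need not be 1. With TMM that median was −1.61 (−7.76 to 0.296) over 14 measured members, 4 of them with 0 counts in hypoxia. With each 0 taken as 3 estimated molecules it was 0.224, so the factor, and the directions that turn with it, are uncertain.

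Inflammatory pathways were sparsely counted in the hypoxia library, as were other genes of their abundance. Of the members counted in normoxia, 2 NF-kB targets were counted in hypoxia against 2 (0 to 5) in matched genes, 2 interferon response genes against 3 (1 to 7), 0 inflammasome genes against 1 (0 to 3) and 4 complement genes against 4 (1 to 7). NF-kB targets had a ratio of 0.461 (0.063 to 1.88), with 6 of 7 measured members lower on reads and 1 neither. Type I interferon response genes had one of 0.423 (0.089 to 1.37), with 12 of 14 lower, 1 higher and 1 neither. Rsad2, an antiviral enzyme gene, had 1228 and 14 counts. The 4 inflammasome genes counted in normoxia, Gsdmd (676), Aim2 (507), Nlrp1b (258) and Nlrc4 (238), had 0 counts in hypoxia. Of the pain-related mediators Tnf and the cathepsin gene Ctss (4825 and 168 counts, 3.35-fold lower on reads) were the 2 counted, and the list's ratio was 0.487 (0.130 to 1.39). Chemokine genes had a ratio of 0.786 (0.175 to 2.65), with Ccl9 higher at 339 and 146 counts and 5 others at 0 in hypoxia, Ccl6 (1574) the most abundant of them, and without Ccl6 the ratio was 1.81 (0.347 to 8.37). MHC class II genes took 0.599% and 0.323% of counts, a ratio of 0.540 (0.264 to 1.02), with Cd74 at 4247 and 103 counts. Complement genes had a ratio of 0.501 (0.184 to 1.16). None of these intervals excluded 1 on total counts. With TMM the upper limits for the interferon, inflammasome, pain-related, MHC class II and complement lists were 0.783, 0.955, 0.796, 0.583 and 0.664, and with housekeeping scaling they lay above 1 and the chemokine ratio was 1.38.

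**Figure D4:**
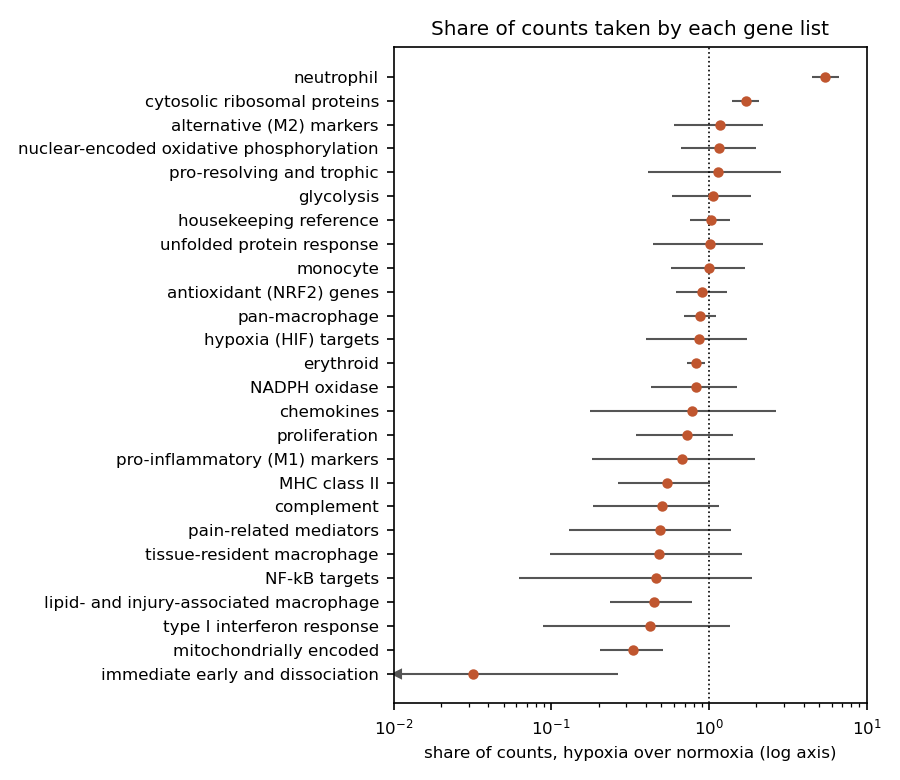
Share of total counts in the hypoxia library over that in the normoxia library (log axis) for each list with at least 10 estimated molecules over both libraries, with 95% intervals on estimated molecules. The neutrophil ratio of 5.48 lies to the right of 1 (dotted line) and the mitochondrial ratio of 0.330 and the immediate early ratio of 0.032 lie to its left, the latter with its lower limit off the axis.

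Over all 4215 genes with at least 50 counts, 500 were higher in the hypoxia library by the size rule, 3192 were lower and 523 met neither. With housekeeping scaling the split was 936 higher and 2692 lower. Of the higher genes 224 had 0 counts in normoxia, and of the lower genes 2883 had 0 counts in hypoxia, so 276 and 309 were counted in both. With intervals on estimated molecules 8 genes were higher and 55 lower under TMM, and 35 and 16 on total counts. A simulation of 2929 genes with no difference called 50 and 1 on total counts, but it counted fewer genes than either library. All 8 and all 16 passed under both scalings. The 8 were S100a9, S100a8, Ngp, Camp, Lcn2, Asns, Dock10 and Ylpm1, and the 16 included mt-Co1, mt-Cytb, Apoe, Ctsb, Hbb-bt, Alas2, Slc4a1, the elongation factor gene Eef1a1 (13932 and 418 counts) and Psap (9005 and 197). Of these Lcn2 (2719 and 1393), Dock10 (0 and 195), Ylpm1 (0 and 188) and Psap were named after their values were seen. Asns, Dock10 and Ylpm1 had 0 counts in normoxia and only 4.59 to 5.00 estimated molecules in hypoxia, with lower limits of 1.18 to 1.34 under TMM. These 3 calls are weak. The simulation with no difference called more genes higher than the 35 found on total counts, so that number is no sign of a difference. It does not speak to single genes. S100a9, S100a8, Ngp, Camp and Lcn2 held 35.7 to 108 estimated molecules in hypoxia, with lower limits of 2.11 to 2.46 under TMM. Across the genes counted in both libraries, Pearson's r of log2 counts was 0.438, and genes are not independent replicates.

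Among genes with at least 200 counts, the 12 highest ratios on reads were led by the proteasome subunit gene Psmb4 (82 counts in normoxia and 152 in hypoxia, 15.9-fold, 12.1 to 21.1 on reads), the splicing factor gene Bud31 (97 and 161, 14.2-fold) and the ATP synthase subunit gene Atp5e (149 and 182, 10.5-fold). The others were Rasgrp4, Kif11, Psme1, Eif4h, Coro1b, Elob, Snrpe, Mycbp2 and Glul, at 9.84-fold to 5.65-fold. On estimated molecules none of the 12 passed with TMM, whereas Psmb4, Bud31, Atp5e, Rasgrp4, Eif4h, Coro1b and Mycbp2 passed on total counts. The 12 lowest all had 0 counts in hypoxia. They were Slc4a1, Fam46c (2992 counts in normoxia), Plbd1 (2735), the spectrin gene Sptb (2456), Ccr2, the histone gene H3f3a (2273), Dusp1, Tmbim6 (2212), Pdia6 (2137), the water channel gene Aqp1 (2125), Tubb4b (1985) and Atp6ap1 (1947).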

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

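The intervals on estimated molecules and the repeats on genes counted in both libraries were chosen after the data were seen, and the other alternatives before. The 500 higher genes became 936 with housekeeping scaling, 959 at 20 counts, 153 at 200 counts, 1147 with no filter, 8 on estimated molecules, 35 on estimated molecules with total counts, and 276 among genes counted in both libraries. The 3192 lower genes became 2086 at 200 counts, 55 and 16 on estimated molecules under TMM and total counts, and 309 among genes counted in both. Filters and the restriction to both libraries change which genes are tested, and the molecule intervals are wider by construction. The M1 median of −8.12 became −6.13 and −4.84 at prior counts of 2 and 5, which act on members at 0, and −0.54 on the single member counted in both. The M2 median of −7.94 turned to 0.37 on the 3 members counted in both, and the M1 minus M2 difference of −0.18 turned to 0.27 at 200 counts, each within an interval so wide that it leaves the sign open. Reversed were the neutrophil list as a mean (−0.70, from 3 members at 0), skeletal muscle at 20 counts and with no filter (2.07 for both, from 1 added gene), nuclear oxidative phosphorylation with housekeeping scaling (0.28) and in genes counted in both (0.094), and the percentile of the unfolded protein response at 200 counts (2.28, the cause was not tested). Housekeeping scaling, which shifts every gene alike, also turned Atp5a1 (0.58), B2m (0.35), Cox4i1 (0.36), H2-Eb1 (0.34), Hbb-bs (0.60), Stmn1 (0.32), mt-Nd1 (0.30) and mt-Nd4 (0.23). For other named genes, 1600 values stayed within their interval and 317 moved. For list medians these were 312 and 125. Of list percentiles 508 kept their side, 20 newly stood apart and 15 no longer did. The planned scaling to the pan-macrophage median was not run, since 15 of its 25 measured members had 0 counts in hypoxia and the prior count would set the factor. No paired analysis was possible because each group has 1 library. Genes below 807 CPM, or 3 estimated molecules in hypoxia, are limited by the untested estimate of reads per molecule.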

Other observations

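The tests of copying, depth, loss of selected genes, blood, antigen-presenting cells and handling in this part were chosen after the results were seen. Genes of dividing cells were present in both libraries. The proliferation list had a ratio of 0.728 (0.343 to 1.43 on estimated molecules), with Mki67 at 2825 counts in normoxia and 58 in hypoxia, Top2a at 1151 and 138 and Rrm2 at 698 and 49. By the size rule 2 of 14 measured members were higher, 10 lower and 2 neither. Genes of the unfolded protein response had a ratio of 1.02 (0.441 to 2.19), and the list lay at percentile 97.9 of random lists but at 2.28 with a minimum of 200 counts, with the asparagine synthetase gene Asns at 0 and 179 counts and the chaperone gene Hspa5 at 3125 and 33. Without Hspa5 the ratio was 2.03 (0.762 to 5.27), or 1.17 (0.437 to 3.02) with TMM and 3.56 (1.33 to 9.22) with housekeeping scaling. Genes of resolution and trophic support had a ratio of 1.15 (0.414 to 2.87), with Anxa1 at 1608 and 283 counts and Grn at 852 and 8, and without Anxa1 the ratio was 0.055, with an upper limit of 1.35, or 0.775 with TMM. With TMM the ratios of these 3 full lists were 0.417, 0.585 and 0.657, and with housekeeping scaling 1.27, 1.79 and 2.01. With TMM the proliferation interval of 0.197 to 0.817 excluded 1.

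B cell genes had a ratio of 0.505 (0.027 to 3.18), with Cd79a at 452 counts in normoxia and 0 in hypoxia, and Ebf1 at 0 and 55. Dendritic cell genes had a ratio of 1.24 (0.023 to 22.1), or 0.713 with TMM, with Irf8 at 168 and 40 counts. The muscle gene Acta1 had 102 and 1 counts and Ckm 0 and 20, and the list lay at percentile 98.3 on its 1 measured member. Of the pericyte and smooth muscle genes, Cspg4 had 81 and 0 counts and Myh11 had 0 and 20, and of the histone genes Hist1h2bc had 128 and 0 and Hist1h4i had 0 and 43. The Y-linked gene Ddx3y had 451 and 59 counts, and the other genes of that list, with Xist among them, had 0 in both. The predicted gene Gm42418 was among the 5 with most counts in each library, at 30389 and 3325.

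Many genes abundant in normoxia were missing from the hypoxia library. Of 977 genes with at least 500 counts in normoxia, 474 (48.5%) had 0 counts in hypoxia, whereas Poisson sampling at the lower depth gives 1.24e-13 such genes, which argues against depth alone. Of 36 ribosomal protein genes at that level 35 were counted in hypoxia, against 23 (17 to 28) in genes matched on normoxia counts, at percentile 100. This cannot decide whether chance loss of few starting molecules was the only cause. Matched genes may owe part of their normoxia counts to chance, at an estimate of 229 reads per molecule. Ribosomal protein genes were listed beforehand, so they could be counted more often under chance loss too. Few molecules copied many times remain a candidate explanation for part of the missing genes. Genes were missing the other way too, as 224 (27.7%) of 810 genes with at least 50 counts in hypoxia had 0 in normoxia. For the immediate early genes, 0 of 15 were counted in hypoxia, against 6 (3 to 10) in matched genes. This argues against chance loss as the only cause for that list. Whether selected genes were lost in the hypoxia sample cannot be told apart from such copying by the housekeeping genes. Of 9 with at least 500 counts in normoxia 8 were counted, against 6 (4 to 9) in matched genes, at percentile 90.3, and so did not stand apart.

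The larger neutrophil share cannot be put down to copying alone by these tests, since the median share ratio of the members counted in normoxia was 4.55, above the upper limit of 1.22 for genes matched on normoxia counts. More blood or marrow of unchanged makeup would bring red cell genes along, but the erythroid ratio was 0.826, below the neutrophil ratio. Neutrophils in the macrophage sample are a candidate source, as S100a8 and S100a9 were at 24549 and 28934 CPM in hypoxia, though 9 of the 13 listed genes were counted in normoxia too. Whether the isolation of the macrophages removed neutrophils is unknown, since how the cells were isolated is not given in the sources used here. Whether the exposure or the sample brought the difference cannot be told apart, with 1 library per group.

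The absence of immediate early genes lay at percentile 0.005 of matched genes, which argues against chance loss of molecules as the only cause. A smaller share of antigen-presenting cells would lower MHC class II genes as much, but the immediate early ratio was 0.059 of the MHC class II ratio, with an upper limit of 0.491 on estimated molecules. Ctss, also on the pan-macrophage list, held 37.1% of the MHC class II counts in normoxia. A smaller share of macrophages was not tested and is not excluded. Of 25 measured pan-macrophage genes 15, Adgre1 and Cd68 among them, were also at 0 in hypoxia, and 10 were counted. Immediate early genes respond to tissue dissociation, so a difference in handling between the samples is a possible explanation, as is the exposure. With 1 library per group these cannot be told apart.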
